A study of Mus musculus with 2 samples.

How the data were processed

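PAR-CLIP libraries of the RNA-binding protein Quaking (QKI) were compared between its isoforms QKI-5 and QKI-6. In PAR-CLIP, cells are fed a photoactivatable nucleoside, usually 4-thiouridine, protein and RNA are crosslinked with light, the protein is immunoprecipitated, and crosslinked uridines appear as T-to-C conversions in the sequenced complementary DNA. The cells were mouse glioblastoma stem cells of a mixed C57B6/FVB background that lacked Qk, Pten and p53, so that the tagged protein was put back into cells without their own QKI. Per the labels, HA-tagged QKI-5 or QKI-6 was overexpressed, the protein was pulled down with an anti-HA antibody, and the RNA was sequenced on a HiSeq2000. There was 1 library per isoform, and no library of untransfected cells, input RNA or control antibody was analysed here.

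The deposited tables list 1 cluster per line, with its position, strand, sequence, reads, conversions, nearest gene, region and overlapping repeat. Per the labels, the authors worked on the mouse genome build mm10 with TopHat2 2.0.8. The cluster caller, its settings, the handling of duplicate and multiply aligned reads, the read layout and the annotation tool were not given in the sources used here. Per the file headers, the reads of a cluster, its conversion positions, its conversion events and its unconverted events at T are raw counts, and no normalization by the authors was found in these deposited counts. Clusters that share a read group often list almost the same number of reads, so summed reads count some reads more than once. Per the file headers each cluster also has a mode score, a score between 0.5 and 1 whose formula was not given, and it was used for a description alone. The other deposited numeric columns, in other units per the file headers, were the distance to the nearest transcription start and a column identical to the read count, and neither was used for a result.

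The QKI-5 table held 20684 clusters in 13250 read groups and the table of QKI-6 held 7145 clusters in 4274 read groups. Summed over clusters, reads came to 55434180 and 47134560, and to 28733570 and 23819958 with each read group counted once. The depth of the whole libraries was not given, so read shares are relative to the reads in listed clusters. The clusters covered 549010 and 190919 nt, with a mean of 2680 and 6597 reads per cluster.

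Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and bedtools 2.31.1. With 1 library per isoform no spread between replicates exists, and no p-value is given. Percentages carry exact Clopper-Pearson intervals, differences of percentages Newcombe intervals, and log2 ratios of read shares exact conditional binomial intervals, each at 95%. These intervals cover counting error alone. They treat clusters or reads as independent, which reads copied from the same molecule and neighbouring clusters on both strands are not, so the spread between repeated experiments is expected to be wider.

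Conversion was the sum of conversion events over all events at T. Regions were taken as the authors annotated them, and again from GENCODE M21, set beside 20000 random positions. The QKI recognition element ACTAAY (ACUAAY in RNA, Y being C or T) was counted in the cluster sequences and in 100 dinucleotide-preserving shuffles of them, and the Pumilio element TGTANATA and the Rbfox element GCATG were counted the same way as controls. All hexamers outside repeats were counted against 20 shuffles. Clusters were called shared when they overlapped by at least 1 bp on the same strand. Reads were summed per gene over clusters on the sense strand of the GENCODE M21 gene. This assignment was chosen after the tables were seen, since the nearest gene in the tables is often not the gene in which a cluster lies. The log2 ratio of read share, QKI-6 over QKI-5, used 0.5 added reads and genes with at least 50 reads over both libraries. A gene was called higher or lower when the interval excluded 0 and the log2 ratio was at least 1 in size.

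The 16 gene lists were lysosome, endosome, receptors, oligodendrocyte and myelin, known QKI targets, neural stem and glioma, RNA-binding and splicing, cytoskeleton and adhesion, cell cycle, nuclear long noncoding RNAs, ribosomal proteins, mitochondrial transcripts, and markers of neurons, microglia, endothelium and pericytes, and fibroblasts. The number of members with a cluster was set among 10000 random lists of protein-coding genes matched on gene length decile. No expression values were given, so the random lists were not matched on expression. Norad was found under its GENCODE name through a synonym.

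Named genes were Qk, the 10 genes with the most cluster reads in each library among genes with an ACTAAY cluster, the 10 genes with the largest log2 ratio in each direction, up to 4 members per list with the most reads in ACTAAY clusters, and the 5 ACTAAY clusters with the most reads in each library. The comparisons, element, gene lists, thresholds, rule for named genes and a first set of alternatives were chosen before the data were examined. Chosen after the data were seen were the 5 genes with clusters in both libraries and the largest ratio in each direction, the 12 genes with the most sense clusters, all antisense counts, the reverse complement of the element, the hexamers, and the counts without clusters of about 1 conversion event per read.

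Alternatives were a minimum of 20 reads, a minimum of 3 conversion positions, the larger set reduced to the size of the smaller, removal of repeats, rRNA and mitochondrial clusters, other definitions of the element, other shuffles, other overlaps, reads or cluster numbers in place of each other, another pseudocount of 5 reads, no minimum of reads, scaling by the median, and random lists matched on 3' UTR length. The search of 20 nt on both sides of each cluster was not run, since no genome sequence was given.

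The methods were tested on simulated data. The 20684 QKI-5 cluster sequences were shuffled with their dinucleotides kept, and ACTAAC was placed in 0, 1 and 5% of them. The ratio of ACTAAY over further shuffles was then 0.922, 2.08 and 5.31. The value of 0.922 thus belongs to shuffled sequences with nothing placed, not to the real clusters. Of 200 random gene lists, 1% lay above the bound of the upper 2.5%. Of 20 lists that mixed members chosen for having a cluster with members chosen for having none, 100% passed. This test used fewer random lists than the results did. In 3000 simulated genes per setting, the intervals of the log2 ratio held the true value in 95.0, 95.4 and 95.4% for true values of 0, 1 and 3. The simulated reads were drawn independently, as the interval assumes. Reads counted more than once, as in the real sums, were not simulated, so this checks the computation alone. As a check of the build, 88.8% of the 464 QKI-5 and 94.9% of the 237 QKI-6 sequences of clusters sense to coding exons were found in the transcripts of that gene.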

Results

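QKI is a STAR-family protein that binds ACUAAY elements in RNA. Its isoforms share the RNA-binding domain and differ in their tails: QKI-5 carries a nuclear localization signal, while QKI-6 is found mainly in the cytoplasm. The listed clusters of both isoforms, expressed in glioblastoma stem cells without their own Qk, were compared for their number, conversion, region, strand, sequence and genes.

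At Qk itself (chromosome 17, 10202601 to 10319854, minus strand), clusters were few and, in QKI-5, mostly on the strand opposite to the gene. QKI-5 had 4 sense clusters with 2264 reads, all in introns, and 8 antisense clusters with 15335 reads. QKI-6 had 1 sense cluster with 32 reads in a coding exon and 1 antisense cluster with 70 reads. The QKI-5 clusters with the most reads at Qk, with 6477 and 6415 reads, lay antisense in a coding exon, at 10238956 to 10238999 and 10239018 to 10239032. The log2 ratio of sense read share, QKI-6 over QKI-5, was -5.89 (95% interval -6.46 to -5.41), with 114 and 29 nt covered and a mean of 566 and 32 reads per cluster. Of the QKI-5 sense reads, 2036 lay in an LTR repeat, and without repeats the log2 ratio was -2.21. No sense cluster at Qk held ACTAAY in either library. The cells lacked Qk and overexpressed a tagged isoform, so coding exon reads at Qk may come from the introduced sequence or from the locus. These cannot be told apart here, so the ratio at Qk cannot be read as a difference in binding.

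QKI-5 had 20684 clusters and QKI-6 had 7145, but the reads were concentrated in few of them. The 20 clusters with the most reads held 32.2% of the QKI-5 reads and 43.2% of the QKI-6 reads. Clusters in rRNA repeats, copies of ribosomal RNA sequence, made up 1.97% (1.78 to 2.17%) of the QKI-5 and 5.72% (5.20 to 6.29%) of the QKI-6 clusters, and held 18.1 and 34.9% of the reads. Clusters in srpRNA repeats, which derive from the 7SL RNA of the signal recognition particle, numbered 26 and 20 and held 11.8 and 10.7% of the reads. The mitochondrial genome had 124 and 106 clusters with 9.69 and 8.45% of the reads. Repeats and mitochondrial sequence together held 43.5% of the QKI-5 and 45.3% of the QKI-6 clusters. The median cluster was 24 nt wide in both libraries, with 974 reads in QKI-5 (quartiles 340 to 2007) and 1707 in QKI-6 (quartiles 550 to 3616). With 1 library each and the whole depth unknown, the difference in the number of clusters has no replicate error to be set against.

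T-to-C conversion, the mark of crosslinked uridines, was sparse in most clusters of both libraries and concentrated in a few rRNA repeats. Summed over all clusters, 0.853% (0.852 to 0.854%) of the 330023467 events at T were conversions in QKI-5 and 1.88% (1.87 to 1.88%) of 252216632 in QKI-6. The median cluster had 0.0413% in QKI-5 and 0.0356% in QKI-6, with a median of 2 and 3 conversion events. A single conversion position was listed for 48.1% of the QKI-5 and 36.8% of the QKI-6 clusters. At most 2 conversion events were listed for 56.2 and 42.5% of the clusters. No rate of sequencing errors was given, so whether conversions in most clusters exceed it was not tested. A listed cluster is therefore not by itself evidence of crosslinking. The cluster with the most conversions in both libraries lay in an rRNA repeat in an intron of Peak1 (chromosome 9, 56223600 to 56223627, plus strand), with 1524749 events for 1541643 reads in QKI-5 and 3030217 for 3058990 in QKI-6. The next lay in an rRNA repeat in an intron of Zc3h7a (chromosome 16, 11144232 to 11144255, minus strand), with 251069 and 491227 events. Then came a further Peak1 cluster in an rRNA repeat (chromosome 9, from 56223645, plus strand), with 233222 and 475242 events. These 3 clusters had the most events and held 71.4% of them in QKI-5 and 84.5% in QKI-6. After them, an rRNA repeat in an intron of Cd44 (chromosome 2, 102829385 to 102829410, minus strand) had 154698 events for 154798 reads and 267373 for 267631. Without repeats, rRNA and mitochondrial clusters, conversion was 0.1001% in QKI-5 and 0.0849% in QKI-6, so the order of the libraries turned. Clusters with over 10% conversion numbered 456 (2.20%) and 184 (2.58%).

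Most clusters of both isoforms were annotated by the authors as intergenic or intronic, and mRNA exons held few. Intergenic clusters made up 52.6% in QKI-5 and 49.95% in QKI-6, a difference of -2.60 percentage points (-3.95 to -1.26), and introns held 38.1 and 37.8% (-0.36 points, -1.66 to 0.95). Coding exons held 3.21% in QKI-5 and 4.703% in QKI-6 (1.49 points higher, 0.963 to 2.06), and 3' UTRs 1.45% (299 clusters) and 1.89% (135 clusters; 0.444 points higher, 0.106 to 0.819). By reads both orders turned: coding exons held 2.09% of the QKI-5 and 1.84% of the QKI-6 reads, and 3' UTRs 0.819 and 0.688%. Promoters held 2.40 and 2.06% of the clusters, transcript ends 1.15 and 1.46%, noncoding exons 0.324 and 0.350%, and 5' UTRs 0.179 and 0.322%. With the GENCODE M21 annotation, coding exons held 4.57% of the QKI-5 and 6.42% of the QKI-6 clusters against 1.49% of random positions, 3' UTRs 2.28 and 2.74% against 1.21%, and introns 44.2 and 43.0% against 41.0%. Of the 946 QKI-5 and 459 QKI-6 clusters in GENCODE coding exons, 51 and 46 lay in Fzd4 alone, and 46 and 24 in Fzd6. The differences between libraries were of a few points, and no replicate shows how far such shares move between repeated experiments.

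**Figure D1:**
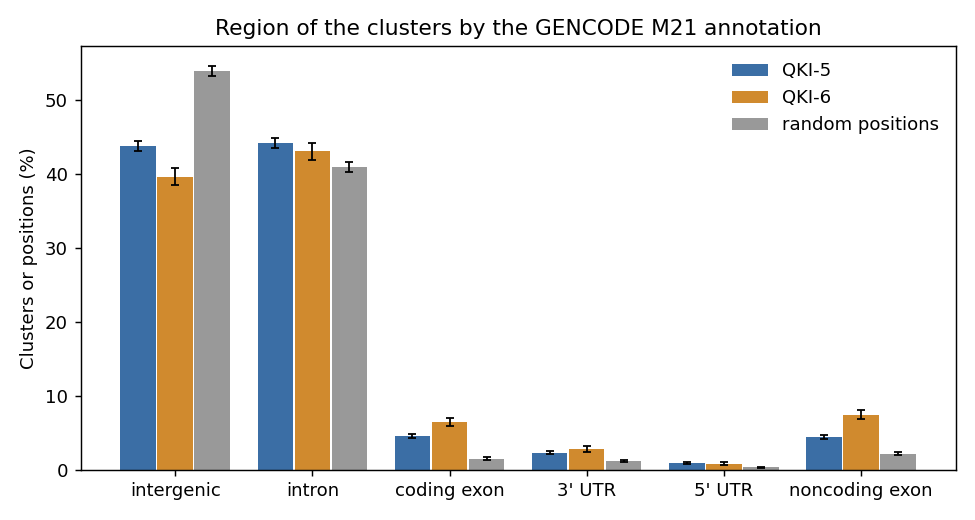
Percent of clusters (bars, vertical axis in percent) in each GENCODE M21 region for QKI-5, QKI-6 and 20000 random genome positions, with 95% Clopper-Pearson intervals as error bars. Introns hold 44.2, 43.0 and 41.0%, and coding exons 4.57, 6.42 and 1.49%.

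Clusters in protein-coding genes lay about as often on the antisense as on the sense strand. Over gene bodies, 4931 QKI-5 clusters were sense and 4688 antisense (51.3% sense, 50.3 to 52.3%), and in QKI-6 1850 and 1724 (51.8%, 50.1 to 53.4%). In coding exons the sense share was 48.9% (45.7 to 52.1%) and 51.6% (47.0 to 56.3%), and in 3' UTRs 48.4% (43.7 to 53.04%) and 49.2% (42.1 to 56.4%). Random positions with a random strand gave 49.7% over gene bodies. Of the antisense clusters in coding exons, 90.7% in QKI-5 and 93.7% in QKI-6 matched the reverse complement of a transcript of the gene, so the listed strand and sequence belonged together. Within 200 nt, 70.9% of the QKI-5 and 75.4% of the QKI-6 clusters had a cluster on the opposite strand. Outside repeats, 2554 pairs of nearest read groups on opposite strands lay within 500 nt in QKI-5, and 97.2% (96.5 to 97.8%) had the plus-strand group on the left. In QKI-6 this held for 95.5% (93.9 to 96.8%) of 842 pairs. The read numbers of both members were within 10% of each other in 89.4% of the QKI-5 and 85.2% of the QKI-6 pairs, against 5.91 and 5.94% after the partners were shuffled. The pairs were looked at after the strand counts were seen, and strands are given as listed in the tables.

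**Figure D2:**
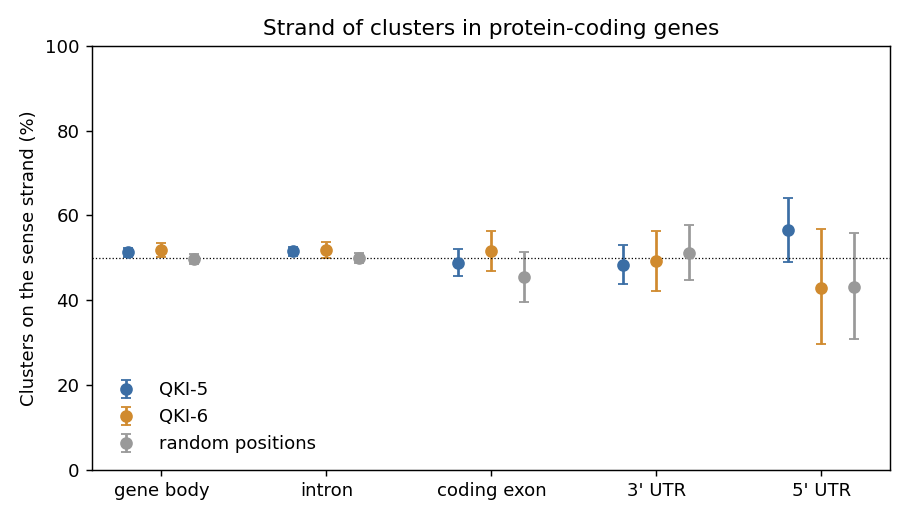
Percent of clusters on the sense strand of protein-coding genes (points, vertical axis in percent, 95% Clopper-Pearson intervals as bars) by region for QKI-5, QKI-6 and random positions, with a dotted line at 50%. Over gene bodies the values are 51.3, 51.8 and 49.7%.

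The QKI recognition element was no more frequent in the clusters than in shuffled sequences of the same composition. ACTAAY occurred in 129 QKI-5 clusters (0.624%, 0.521 to 0.741%) against a mean of 155 in 100 shuffles, a ratio of 0.833 (0.696 to 0.989). In QKI-6 it occurred in 41 (0.574%, 0.412 to 0.778%) against 58.3, a ratio of 0.703 (0.505 to 0.953). In both libraries 99 of the 100 shuffles had at least as many clusters with ACTAAY. ACTAAC alone gave ratios of 0.771 and 0.641, and ACTAAY with a nearby TAAY 15 and 2 clusters, ratios of 0.789 and 0.257. The reverse complement of ACTAAY gave 0.886 (0.765 to 1.02) and 1.04 (0.821 to 1.29). Of the controls, the Pumilio element gave 1.23 (0.891 to 1.66) and 1.15 (0.628 to 1.93), and the Rbfox element 0.976 and 1.02. Among clusters sense to protein-coding genes, ACTAAY occurred in 27 of 5084 in QKI-5 and 8 of 1895 in QKI-6, and in 3' UTRs in 2 of 236 (against 0.97 in shuffles) and 1 of 97 (against 1.08). Of clusters found in both libraries, 6 of 626 in QKI-5 and 6 of 639 in QKI-6 held it, against 4.23 and 4.77 in shuffles. Of the clusters with over 10% conversion, 0 of 456 and 0 of 184 held it against 1.78 and 0.71, too few to tell from chance. With at least 3 conversion positions the ratios were 1.004 in QKI-5 and 0.550 in QKI-6. Clusters have a median width of 24 nt, so an element beside a cluster was not counted.

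**Figure D3:**
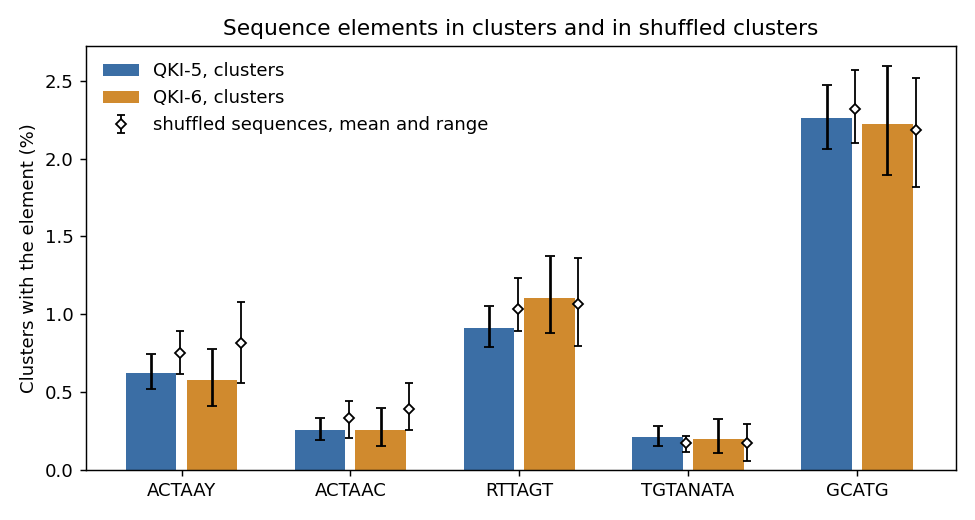
Percent of clusters with each sequence element (bars, vertical axis in percent, 95% Clopper-Pearson intervals) for QKI-5 and QKI-6, with the mean and range of 100 dinucleotide shuffles as diamonds and bars. RTTAGT is the reverse complement of ACTAAY, which occurs in 0.624% of the QKI-5 and 0.574% of the QKI-6 clusters.

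The ACTAAY clusters with the most reads lay in mitochondrial rRNA, introns and intergenic sequence. In QKI-5 the first was antisense to the mitochondrial 16S rRNA gene mt-Rnr2 (chromosome M, 1792 to 1858, minus strand), with 18610 reads and the sequence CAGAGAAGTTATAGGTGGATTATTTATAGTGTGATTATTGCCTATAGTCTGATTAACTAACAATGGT. The next were GACTAATCGAACCATC in an intergenic rRNA repeat (chromosome 18, 68692065 to 68692080, plus strand; 5068 reads) and TTACTAACAGCAGAGTC (chromosome 10, 4393662 to 4393678, minus strand; 4825 reads), annotated by the authors as intergenic and antisense to an exon of Gm21781 in GENCODE. They were followed by ATTACTAACAACTT in a LINE repeat in an intron of Cped1 (chromosome 6, 22114659 to 22114672, plus strand; 4488 reads) and the intergenic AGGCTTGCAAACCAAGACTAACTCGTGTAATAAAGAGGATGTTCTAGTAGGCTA (chromosome 3, 22946838 to 22946891, minus strand; 3974 reads). In QKI-6 the first were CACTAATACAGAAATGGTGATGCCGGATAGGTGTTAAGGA in an intron of Pa2g4 (chromosome 10, 128559557 to 128559596, minus strand) and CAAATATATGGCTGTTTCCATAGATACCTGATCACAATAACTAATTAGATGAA in an intron of Ntm (chromosome 9, 29817716 to 29817768, minus strand), with 6981 reads each, both sense. Then came CTGAAACTAATTTC in an intergenic LTR repeat (chromosome 18, 32902467 to 32902480, minus strand; 6781 reads), ATTGGGTACTAACATTGG (chromosome 3, 128684139 to 128684156, minus strand; 4908 reads), intergenic for the authors and antisense to an intron of Gm43824 in GENCODE, and TAACTAACAATGGTTA antisense to mt-Rnr2 (chromosome M, 1790 to 1805, minus strand; 4781 reads).

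Among genes with an ACTAAY cluster, H3f3a, which encodes a histone H3.3, had the most QKI-5 sense reads, 34737, of which 3076 were in ACTAAY clusters. Lars2, the mitochondrial leucyl-tRNA synthetase, had 31846 (569 in ACTAAY clusters) and the growth factor receptor gene Fgfr2 28225 (247). They were followed by Cped1 with 13451, Lrp1b with 11142, Sh3bp4 with 10876, Psme4 with 10513, Gm15564 with 8956, Cfap54 with 8811 and Ank2 with 8669 QKI-5 sense reads. In QKI-6 Lars2 led with 26915 sense reads (38 in ACTAAY clusters), followed by Rab38 with 9031, the synaptic adhesion gene Nlgn1 with 8748, Ntm and Pa2g4 with 6981 each, Kif6 with 5123, mt-Nd4 with 3844, Gm15564 with 3098, Gm28453 with 2880 and Gm45740 with 1020. Lars2 and Gm15564 were in both sets of 10. In QKI-5, repeats held 15663 of the H3f3a and 21476 of the Fgfr2 sense reads, and all of those of Cped1 and Gm15564. In QKI-6 they held 30134 of 37079 Fgfr2 sense reads and all of those of H3f3a, Ank2, Kif6 and Gm15564. The annotated Fgfr2 gene runs from 130162451 to 133123350 of chromosome 7, and 14 of its 19 QKI-5 sense clusters lay in introns. Reads were summed over this whole span. The sense reads of Lars2, Sh3bp4, Rab38, Ntm, Pa2g4, Gm28453 and Gm45740 all lay outside repeats. The log2 ratio of read share was -0.01 (-0.03 to 0.01) for Lars2, -0.47 for H3f3a, 0.63 for Fgfr2, -0.55 for Ank2, 0.25 for mt-Nd4, -3.51 for Lrp1b, -1.30 for Gm15564, 4.45 (4.32 to 4.59) for Nlgn1 and 1.80 for Kif6. The means behind these ratios were 1238 and 276 reads per cluster over 248 and 63 nt at Lrp1b, and 234.5 and 2187 over 60 and 108 nt at Nlgn1. By number of clusters in place of reads, Lars2 (0.80), Lrp1b (0.0929) and Gm15564 (1.53) were on the other side of 0. Their QKI-5 and QKI-6 clusters numbered 7 and 4, 9 and 3, and 3 and 3. For Lars2 and Gm15564 the change of sign thus came from scaling by the unequal totals of clusters. For Lrp1b that scaling alone leaves the log2 ratio just under 0, and the 0.5 added before the log2 turned its sign. From ACTAAY clusters alone, the log2 ratio was -3.65 for Lars2, 1.89 for mt-Nd4 and -0.15 for Gm15564. With the QKI-5 set reduced to the size of the QKI-6 set, H3f3a had -0.05. On the antisense strand, H3f3a had 28372 reads in QKI-5 and 27051 in QKI-6, Lars2 54819 and 9431, Nlgn1 5769 and 8679, Ank2 12958 and 0, and Kif6 3446 and 0. With the clusters of both strands, the log2 ratio was -1.02 for Lars2, 1.72 for Nlgn1, 0.22 for Kif6 and -1.87 for Ank2, and with each read group counted once it was 0.26 for Kif6, 0.26 for Ank2, -0.11 for Gm15564 and -0.19 for mt-Nd4. On the antisense strand alone it was -0.18 for mt-Nd4 and 0.17 for H3f3a.

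Few clusters were shared between the isoforms, and those that were came mostly from structural RNA. Of the QKI-5 clusters, 626 (3.03%, 2.80 to 3.27%) overlapped a QKI-6 cluster on the same strand, and 639 (8.94%, 8.29 to 9.63%) of the QKI-6 clusters overlapped one of QKI-5, against a mean of 1.05 QKI-6 clusters in 20 random placements. They held 46.8% of the QKI-5 and 67.1% of the QKI-6 reads. Clusters in rRNA repeats made up 45.7 and 47.4% of the shared clusters, mitochondrial clusters 62 and 64, satellite repeats 61 and 57, and snRNA repeats 51 and 51, while 116 and 112 lay in no repeat. Without repeats, rRNA and mitochondrial clusters, the shared clusters came to 0.958 and 2.74%. Overlap with the opposite strand was 2.21 and 6.31%. Of 21991 protein-coding genes, 2434 had a sense cluster in QKI-5, 974 in QKI-6 and 347 in both, against 107.8 from the product of both shares and 255.5 with gene length taken into account. Antisense clusters gave 334 genes in both against 239.8, so the excess was of similar size on both strands.

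Most genes had clusters in a single library. Of 3709 genes with at least 50 reads, 443 had sense clusters in both libraries, 2523 in QKI-5 alone and 743 in QKI-6 alone. By the size rule, 931 genes were higher in QKI-6 and 2650 lower, of which the 743 and 2523 with clusters in one library alone pass by construction. Of the genes in both, 188 were higher and 127 lower. By number of clusters in place of reads, 118 genes were higher and 2 lower. These numbers were scaled by totals of 20684 and 7145 clusters, so equal numbers in both libraries give a ratio above 0. The split by cluster number therefore cannot show a direction. With the QKI-5 set reduced to the size of the QKI-6 set, 1013 were higher and 953 lower, without the excess of lower genes. The largest QKI-6 read numbers without a listed QKI-5 cluster were those of Tnrc18 (31743 sense reads), the translation factor gene Eif4g2 (21575, the same clusters being counted for the snoRNA gene Gm23262 within it), Zbtb39 (19788), Aldh1a1, a retinaldehyde dehydrogenase gene (18934), Polr1a, the largest subunit of RNA polymerase I (18266), Abi2 (18189, in the 3' UTR), Pacsin2 (17543), Ubxn7 (17456) and Plscr4 (16701). Without a listed QKI-6 cluster, the largest QKI-5 read numbers were those of Zfp300 (20420), the axon guidance gene Slit3 (19941), the elongation factor gene Supt6 (19580), Zfp608 (19112), the glycolytic enzyme gene Pgk1 (18434, in the 5' UTR, with 10 QKI-6 clusters listed just upstream of the annotated gene start), Frk (16492), AC142100.3 (16269), Epb41l1 (16080), the long noncoding RNA Pvt1 (15886) and the kinesin light chain gene Klc1 (15876). Each of these 20 genes had between 3 and 7 sense clusters in its library. Most also had antisense reads there, such as Polr1a with 18197 and Tnrc18 with 19146 in QKI-6 and Supt6 with 19418 in QKI-5, while Zbtb39 and Zfp300 had 0. In QKI-6, repeats held 12868 of the sense reads of Tnrc18, 13835 of those of Eif4g2 and Gm23262, 11687 of Pacsin2 and 11160 of Plscr4. In QKI-5 they held 4089 of Slit3, 7707 of AC142100.3 and 6231 of Pvt1. The sense reads of the other genes named here all lay outside repeats.

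Genes listed in both libraries, chosen after their values were seen, also included some with near-zero reads on one side. Dclk1, a doublecortin-like kinase gene, had 5 QKI-5 and 15002 QKI-6 sense reads (log2 ratio 11.65), Nedd4 6 and 6381 (10.17), Lmo2 6 and 6045 (10.10), Atp7a 12 and 10789 (9.99) and Olfr472 5 and 3694 (9.63). In the other direction, the snRNA gene Gm25360 had 37414 and 5 (-12.50), the chromatin remodeller gene Chd7 6539 and 12 (-8.80), Dapk1 2728 and 6 (-8.48), Abr 3601 and 14 (-7.72) and Elmo1 10918 and 64 (-7.17). Dclk1 had 1 cluster of 18 nt in QKI-5 and 4 over 114 nt in QKI-6, with a mean of 5 and 3751 reads, and Elmo1 4 over 106 nt and 2 over 36 nt, with a mean of 2730 and 32. Antisense reads were 0 and 14027 at Dclk1, and 14248 and 0 at Elmo1. In the library with more reads, repeats held all sense reads of Olfr472, Gm25360, Dapk1 and Abr. They held 1269 of those of Dclk1 and 1879 of Elmo1, and none of those of Nedd4, Lmo2, Atp7a and Chd7. By number of clusters in place of reads, Gm25360, Dapk1, Abr and Elmo1 were on the other side of 0 (0.31, 1.53, 0.31 and 0.69). None of these genes had more clusters in QKI-6 (3 and 1, 1 and 1, 3 and 1, 4 and 2). For Dapk1 and Elmo1 the sign there came from scaling by the unequal totals of clusters. For Gm25360 and Abr (3 and 1 clusters) that scaling alone leaves the log2 ratio just under 0. The 0.5 added before the log2 turned their sign. The median log2 ratio of the genes in both libraries was 0.456. Across these 443 genes, which are not independent replicates, log2 reads correlated between libraries with a Pearson coefficient of 0.444 and a Spearman coefficient of 0.301. With antisense in place of sense clusters, 872 genes were higher and 2609 lower.

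Of the 16 gene lists, 2 had more members with a QKI-5 sense cluster than the bound of the upper 2.5% of random lists of like gene length, and 1 in QKI-6. Cytoskeleton and adhesion had 12 of 30 members with a QKI-5 cluster against a random mean of 6.38 (percentile 99.5), among them Macf1 (14466 sense reads), Map2 (8583), Dst (8419) and Add3 (7421), and 5 in QKI-6 against 2.68 (92.4). Its antisense clusters covered 10 members in QKI-5 (96.1). Mitochondrial transcripts, taken as background, had 10 of 15 members in QKI-5 against 0.275 and 7 in QKI-6 against 0.152 (percentile 100 in both). The mitochondrial rRNA gene mt-Rnr2 had 2573291 sense and 2600044 antisense reads in QKI-5, and 1876313 and 1919763 in QKI-6. In the lists with clusters in at least 3 members in both libraries, the median log2 ratio was 1.14 for cytoskeleton and adhesion (4 members, random median 0.453, percentile 67.4) and 0.11 for mitochondrial transcripts (4 members, random median 0.482, percentile 37.9).

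Known QKI targets had 5 of 11 members with a QKI-5 sense cluster against a random mean of 2.14 (percentile 98.6, equal to the upper 2.5% bound of 5 and not above it): Macf1, Add3, the myelin genes Mbp (3444 sense reads) and Mag (223), and Hnrnpa1 (288). In QKI-6 Macf1 alone had one, with 421 reads (log2 ratio -4.87, from 4 clusters over 93 nt to 1 over 29 nt). The same 5 members were above a bound of 4 with at least 20 reads, without repeats, rRNA and mitochondrial clusters, and with random lists matched on 3' UTR length (percentiles 98.7, 99.6 and 98.7), while with at least 3 conversion positions or the set reduced 2 members remained, below the bound of 3. Antisense clusters covered 3 members in QKI-5, and no sense cluster of a known target held ACTAAY in either library. Oligodendrocyte and myelin genes had 3 of 16 members in QKI-5 against 1.46 (Mbp, Mag and Sox10) and 1 in QKI-6 (Gpr17, 8305 reads). Lysosome genes, which encode degradative enzymes and membrane proteins of that organelle, had 7 of 39 in QKI-5 against 3.21 (percentile 97.8, equal to the bound of 7) and 8 on the antisense strand (99.3), with Glb1 at 6412 sense and 9493 antisense reads. QKI-6 listed 1 lysosome member, Hexb, with 18836 reads against 19457 in QKI-5. Without repeats, rRNA and mitochondrial clusters, 4 lysosome members remained in QKI-5 and 0 in QKI-6, so the Hexb cluster of QKI-6 lies in a repeat. Endosome genes had 8 of 40 in QKI-5 against 4.71 and 1 in QKI-6 (Stam), and receptors 5 of 25 against 6.61 and 2 against 2.72.

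Neural stem and glioma genes had 2 of 20 members in QKI-5 against 2.04 and 3 in QKI-6 against 0.863 (percentile 97.4): the stem cell factor gene Sox2 (1003 sense reads), Msi2 (7124) and Cd44 (267631, in an rRNA repeat). RNA-binding and splicing genes had 8 of 35 in QKI-5 against 5.04 and 4 in QKI-6 against 2.03, with Hnrnpm at 16075 reads in QKI-6. Cell cycle genes had 4 of 27 in QKI-5 against 2.34, with Pcna at 11463 reads, and 2 in QKI-6 against 0.935. In 3' UTRs, cell cycle was the 1 list above the bound in QKI-5, with Ccnd1 (4620 reads) and Cdk1 (162) against a mean of 0.160 (percentile 99.4), and Ccnb1 (1180) had 3' UTR clusters in QKI-6. Nuclear long noncoding RNAs had 2 of 10 in QKI-5, Malat1 and Neat1, against 0.610, and 1 in QKI-6. Malat1 had 9 and 6 clusters with 10528 and 20317 reads (log2 ratio 1.18, over 283 and 206 nt) on the sense strand, and 11948 and 7892 reads on the antisense strand, which ran the other way. Ribosomal protein genes had 0 of 22 in QKI-5 against 0.449 and 1 in QKI-6 (Rps18). Markers of other cell types gave 4 of 12 for neurons in QKI-5 against 2.25 and 1 in QKI-6, 3 of 12 for microglia against 1.47 and 1, 2 of 11 for endothelium and pericytes against 2.20 and 2, and 0 of 10 for fibroblasts in both libraries. With ACTAAY in the cluster, the mitochondrial list was the 1 list above the bound in each library, through mt-Nd4, and Fgfr2 was the other list member with such a cluster. The random lists were not matched on expression, which the tables do not give.

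Among the 12 genes with the most sense clusters, chosen after the values were seen, Fzd4 and Fzd6 stood apart by where their clusters lay. Both encode Frizzled receptors of Wnt signalling. Fzd4 (chromosome 7, 89404355 to 89413134, plus strand) had 17 sense and 34 antisense clusters in QKI-5 and 24 and 22 in QKI-6, with 106311 and 116184 sense reads (log2 ratio 0.36, over 490 and 743 nt) and 173846 and 111550 antisense reads. The Fzd4 log2 ratio was -0.41 on the antisense strand and -0.06 with both strands, so its sign depended on the strand. All 51 and 46 Fzd4 clusters lay in coding exons, and they covered 70.02 and 61.7% of the coding bases. Fzd6 (chromosome 15, 39006034 to 39038188, plus strand) had 25 sense and 21 antisense clusters in QKI-5 and 11 and 13 in QKI-6, with 55148 and 38188 sense reads (log2 ratio -0.30, over 801 and 286 nt) and 52471 and 41710 antisense reads. The Fzd6 log2 ratio was -0.10 on the antisense strand and 0.38 by number of clusters in place of reads. That positive value came from scaling by the unequal totals of clusters, since QKI-5 had more sense clusters (25 against 11). All 46 and 24 Fzd6 clusters lay in coding exons, covering 54.6 and 28.4% of the coding bases. No cluster lay in the UTRs of either gene, although these are longer than the coding sequence (5109 against 1611 nt in Fzd4, 2473 against 2190 nt in Fzd6). The other genes of this set were the rRNA and repeat loci CT010467.1, Gm42418, Gm26917 and Gm26870, mt-Rnr2, and Rbfox1, Gm20388, H3f3a, Fgfr2 and Pde4d. Cluster numbers were not scaled by gene length, and some of these genes are very long. Gm20388 runs from 119910841 to 124345722 of chromosome 8 and Fgfr2 from 130162451 to 133123350 of chromosome 7. Gm42418, within the rRNA gene CT010467.1 on the opposite strand, had a log2 ratio of 1.47 on the sense strand and -1.44 on the antisense strand. Its sense clusters are antisense to CT010467.1 and the reverse, so the ratios of these genes are not separate observations.

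**Figure D4:**
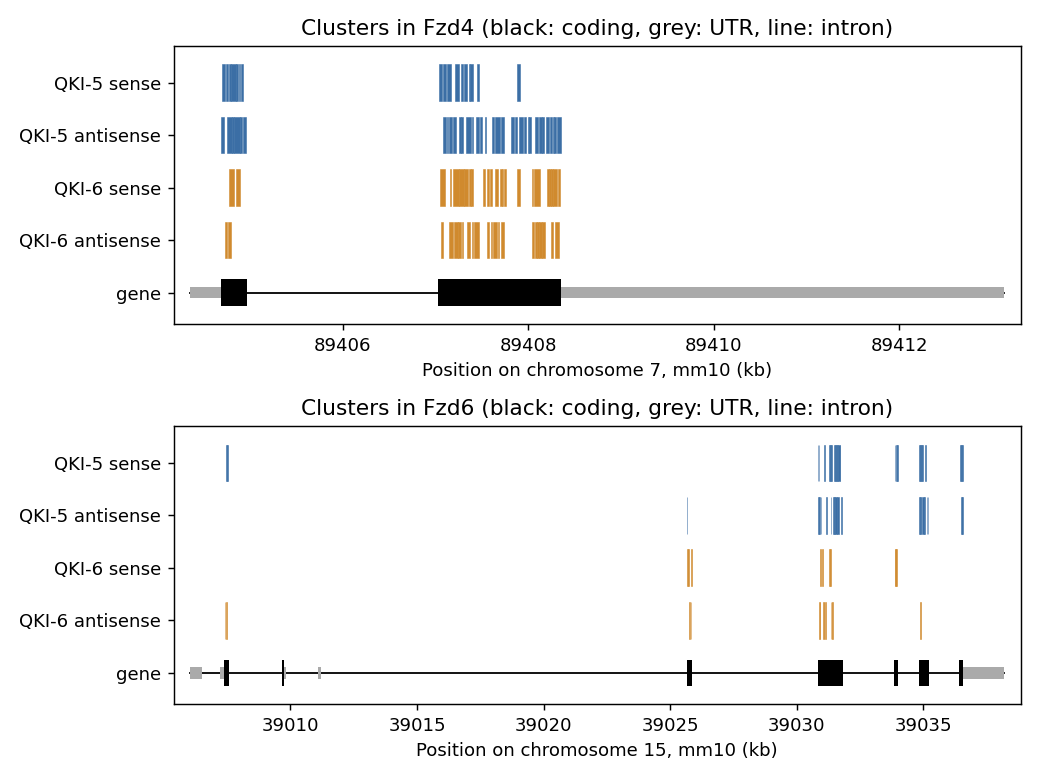
Clusters in Fzd4 and Fzd6 along the mm10 position (horizontal axis in kb), for QKI-5 and QKI-6 on the sense and antisense strand, above the gene with coding sequence in black, UTRs in grey and introns as a line. All 97 clusters in Fzd4 and all 70 in Fzd6 lie in coding exons.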

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

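Of the results that answer a comparison, 61 values under alternatives stayed within their interval or, for counts, within 1.5 times, 41 moved and 2 reversed; of the values for single genes and lists, 291 stayed, 167 moved and 9 reversed. A value was counted as reversed when it had passed the size rule, or for regions its interval excluded 0, and its sign changed. Sign changes of other values were counted as moves. Intervals cover counting error alone and are narrow, so many moves are small. The alternatives chosen after the data were seen were those on antisense or both strands, on read groups counted once, and on clusters with about 1 conversion event per read. A minimum of 20 reads moved no result that answers a comparison. With at least 3 conversion positions, clusters numbered 6042 and 2926, conversion was 1.05 and 2.12%, the ratios for ACTAAY were 1.004 in QKI-5 and 0.550 in QKI-6, 4.14% of QKI-5 clusters were shared, and 592 genes were higher and 1261 lower. With the larger set reduced to the size of the smaller (7145 clusters), QKI-5 conversion was 0.996%, 5.71 and 5.84% were shared, the differences were -1.19 points for intergenic and 0.924 for coding exons, 1013 genes were higher and 953 lower, and 4 lists passed in QKI-5 (endosome, cytoskeleton and adhesion, nuclear long noncoding RNAs and mitochondrial transcripts). Without repeats, rRNA and mitochondrial clusters, 11691 and 3906 clusters remained, conversion was 0.1001 and 0.0849%, 0.958 and 2.74% were shared, coding exons differed by 2.93 and 3' UTRs by 0.822 points, 0 lists passed in QKI-6 and 2 in QKI-5 (known QKI targets, and cytoskeleton and adhesion), and Gm42418 reversed to -3.73. Fewer clusters enter in each of these sets by construction. Without clusters of about 1 event per read, conversion was 0.268 and 0.512%. Mononucleotide shuffles gave ACTAAY ratios of 0.569 and 0.504. With dinucleotide shuffles, ACTAAY with TAAY gave 0.257 in QKI-6. An overlap of 50% of both clusters gave 2.05 and 5.93% shared, and within 50 nt 4.08 and 11.4%. GENCODE regions gave -4.12 points for intergenic. By reads in place of clusters, introns differed by 4.65 points, and coding exons (-0.251) and 3' UTRs (-0.131) reversed. ACTAAY clusters alone left 9 genes higher and 32 lower. By number of clusters in place of reads, 118 were higher and 2 lower, and the log2 ratio reversed for Abr (0.31), Dapk1 (1.53), Elmo1 (0.69), Gm15564 (1.53), Gm25360 (0.31), Gm26870 (0.80) and Lrp1b (0.0929). Of the ratios that had not passed the size rule, those of CT010467.1 (0.47), Fzd6 (0.38), Gm26917 (1.08), Lars2 (0.80) and mt-Rnr2 (2.06) changed sign there. Scaling by 20684 and 7145 clusters puts equal numbers above 0. Of all these genes mt-Rnr2 alone had more clusters in QKI-6 (29 against 20). The other sign changes by cluster number came from that scaling, except at Abr, Gm25360 and Lrp1b. At these the scaling alone leaves the log2 ratio just under 0, and the 0.5 added before the log2 turned the sign. Antisense in place of sense clusters reversed Gm42418 (-1.44), and of the ratios that had not passed the size rule, CT010467.1 (1.31), Fzd4 (-0.41), H3f3a (0.17), Pde4d (-1.65) and mt-Nd4 (-0.18) changed sign. Such sign changes also occurred for CT010467.1, Fzd4 and Pde4d with both strands, for Ank2, CT010467.1, Gm26917, Lars2, Pde4d, mt-Nd4 and mt-Rnr2 with each read group counted once, for CT010467.1, Fzd6, Gm26917, Lars2 and Pde4d without repeats, rRNA and mitochondrial clusters, for Pde4d and mt-Rnr2 with at least 3 conversion positions, and for Gm26917 with the larger set reduced. With random lists matched on 3' UTR length, 2 lists passed in QKI-6 (cytoskeleton and adhesion, mitochondrial transcripts), and in QKI-5 known QKI targets passed as well, as they did with at least 20 reads. Scaling by the median shifted every log2 ratio by 0.456, so a ratio between 0 and that value changed sign by construction. Beyond the smaller sets named, the cause was not tested. The search of 20 nt on both sides was not run, since no genome sequence was given. The unknown depth of the libraries leaves open whether a gene without a listed cluster was unbound or under the caller's limit.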

Other observations

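All tests and loci in this part were chosen after the results were seen. Several single loci held many clusters in at least 1 library. At Pgk1, a glycolytic enzyme gene, 17 QKI-5 clusters (9 on the plus and 8 on the minus strand, median 4606 reads) lay between positions 106186770 and 106187210 of chromosome X, and 13 of them lay upstream of the gene start at 106187100. QKI-6 had 10 clusters there (median 4518 reads), between 106186723 and 106187076 and all 10 starting upstream, and no cluster of this window lay in the rest of the gene. At H3f3a and its flanks, QKI-5 had 77 clusters, 32 of them in repeats, over chromosome 1 from 180799171 to 180819809, and QKI-6 had 15, 11 of them in repeats. At Rbfox1, a neuronal splicing factor gene, QKI-5 had 60 clusters, 31 on the plus and 29 on the minus strand and 11 in repeats, and QKI-6 had 6, all 6 in repeats. At Lars2, the 12 QKI-5 clusters lay in the 3' UTR between 123461805 and 123462168 of chromosome 9 and the 8 QKI-6 clusters between 123461820 and 123462187. Outside repeats, the hexamers with the highest ratio over shuffles were ACGGAG in QKI-5 (44 clusters against 19.8) and CCACGT in QKI-6 (30 against 5.9), while ACTAAC ranked 3914 and 2989 among all hexamers.

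Clusters in protein-coding genes were about as frequent antisense as sense. Binding to the genes' own transcripts, the biological explanation, would give neighbouring read groups on opposite strands no like read numbers if the strand of the RNA were kept, and 89.0% (87.5 to 90.3%) of 1968 such pairs in genes were within 10% of each other, against 6.25% with shuffled partners; annotated genes on the other strand lay over 7.31% (6.57 to 8.11%) of the antisense clusters, so both are argued against as the whole cause, while binding with the strand lost stays open. A candidate explanation that stays open is that both ends of the same fragments were counted as separate reads, since 96.8% (96.1 to 97.4%) of 3396 neighbouring read groups on opposite strands faced each other, with a median span of 135 nt in QKI-5 and 129.5 nt in QKI-6 and nearly equal reads. If so, the listed strand may not be that of the RNA, and the labels do not give the read layout that would settle it. Before the facing pairs were looked at, 2 other explanations had been tested for this pattern. Mature mRNA sequenced without strand was argued against by 24.9% (24.1 to 25.9%) of gene clusters in exons against 9.75% of random positions. For DNA fragments from across the genome, the density ratio of genes over intergenic sequence was 2.62 in QKI-6 and 2.19 in QKI-5. A ratio under 2 was set to speak for DNA fragments and a ratio over 3 against them. Both tests used clusters outside repeats and mitochondrial sequence, while the random positions they were set against included repeats. The density ratio thus compared unlike sets and cannot decide, so DNA fragments stay open.

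Clusters in Fzd4 and Fzd6 covered coding sequence and, apart from 2 nt, no other part of these genes. Whole genomic copies of the genes as the source are argued against by the observation itself, since by length 144.4 clusters would fall in UTRs and introns and 0 were seen. By length 110.9 would fall in the UTRs of the genes' own mRNA, but binding of that mRNA in its coding sequence alone is not excluded and stays open. Another candidate source that stays open is DNA or RNA of a construct with the coding sequences, since both libraries together covered 71.5% of the coding bases of Fzd6 and 87.2% of those of Fzd4 and reached at most 2 nt outside. The labels name no such construct.

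The summed conversion rested on few clusters. The 3 clusters with the most events held at least 71.4% of them in each library, which restates the pattern, so photo-crosslinking as its source stays open. Another candidate explanation that stays open is a fixed base difference between the sequenced molecules and the reference, since QKI-5 clusters with about 1 event per read that overlapped a QKI-6 cluster had a median of 0.998 events per read there too, and 41 of 42 had at least 0.5. Among QKI-5 clusters under 0.1 events per read this held for 4 of 525. The design names no biological difference for the sum.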
